A study of Mus musculus with 3 samples.

How the data were processed

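Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing in double-negative thymocytes of wild-type C57BL/6J mice. Per the labels' protocols, cells lacking CD4 and CD8 were sorted from thymus, fixed with formaldehyde, and their chromatin was first captured with an antibody against histone H3. Adapters were attached to the captured chromatin, which was then precipitated with an antibody against H3K27ac. The labels give 2 H3K27ac replicates and 1 input sample, taken before the second antibody. The input was not analysed here, so no background measured in the same way stands beside the values.

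Reads were aligned with Bowtie2 to mm10 and peaks were called with MACS 1.4.2, per the submitters' processing notes. The deposited lists have the 9-column broad peak layout that MACS2 writes, so the version that made them is uncertain. The peak names in the deposited files carry one library index each and the word rmdup, so peaks were called per sample after removal of duplicate reads. The peak cutoff and the use of the input as control are not given in the sources used here. The fold enrichment of each peak is a ratio computed by the authors' caller. The −log10 p-value and −log10 q-value of each peak were deposited by the authors as well. The score column that the authors deposited is 10 times the −log10 q, cut to a whole number, and entered no test. These values are the authors' own and were used only to describe, rank or filter peaks, and to correlate the folds of shared peaks. The files hold no read counts, so the depth per sample is unknown and no counting interval can be given for a peak.

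Coordinates are those of mm10, counted from 1. Gene positions came from a RefSeq gene table of the same build (GRCm38.p6). That table gives no strand and no transcript starts. The planned promoter, within 1 kb of any transcript start, was therefore replaced by a window of 1 kb around either annotated end of a gene, called a gene end below. A gene-end peak can thus lie at the 3' end of a gene or at the start of a neighbour. Of 21887 protein-coding genes, each counted once per symbol, a gene was called acetylated when each replicate had a gene-end peak. Acetylated length is the number of bp covered by peaks of both replicates within 25 kb of a gene end, taking the larger of the ends. Exons and introns could not be separated, and regions were placed at gene ends, elsewhere in protein-coding genes, in other annotated genes or outside genes, by their centre.

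Peaks on the assembled chromosomes were compared between replicates by overlap of at least 1 bp, against 1000 circular shifts of one list within each chromosome (one-sided). Folds of peaks that paired one to one were correlated across peaks, which are not independent replicates, with 100000 permutations (two-sided). For 18 gene lists with 270 entries, of which 269 matched a protein-coding gene, two-sided Fisher's exact tests compared members with all other protein-coding genes. Benjamini-Hochberg adjustment ran over the 18 lists, over the 3 direct comparisons between lists, and over the lists with at least 3 acetylated members for length. Length was tested with 100000 random lists (two-sided permutation test). Covered bp in antigen receptor loci were ranked among 10000 random windows of the same size on the same chromosome. Regions with peaks of both replicates were joined within 12.5 kb, scored by width times fold, and called large above the tangent point of the rank curve in both replicates. The lists, tests and alternatives were fixed before the data were examined.

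Genes were named by a rule fixed at the same time. It takes the 3 members of each discussed list with the greatest acetylated length. It adds the acetylated members of lists where at most 1 in 4 were acetylated, and those without a peak where at least 3 in 4 were. It further takes protein-coding genes with an end in the 20 largest joined regions, the constant regions and flanking genes of the receptor loci, and the genes of the 5 tallest shared peaks. One gene that the rule takes is not reported here.

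Alternatives were a stricter q of 1e-05, the 10000 peaks of smallest p (replicate 2 has fewer and stayed whole), stricter overlap with 100 shifts, a gene-end window of 2.5 kb, a peak in either replicate, each replicate alone, other windows, other joining distances, another region score, random positions and a background without chemosensory receptor genes. Chosen after seeing the data were runs without chromosomes 6, 9, 14 and 17, and with q of at most 0.05. The 5' end alone and a stratification by CpG content were planned and not run, since strand and genome sequence were not used here.

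The list test was checked on simulated data over 21887 genes. Lists of 15 genes raised to a 60% share were found in 86% of 100 simulations, lists of 30 in 99%, and 7 of 1600 unchanged lists were called. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Nothing in the labels says that the replicates came from separate animals, so their differences may be technical. The p-values over genes or peaks describe these lists and say nothing about animals.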

Results

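The data are lists of H3K27ac peaks from 2 replicates of sorted double-negative thymocytes, the stage at which Tcrb, the gene of the T cell receptor beta chain, is rearranged. Replicate 1 had 12377 peaks on the assembled chromosomes and replicate 2 had 9477. They covered 9.93 Mb and 6.85 Mb, with median widths of 615 bp and 561 bp. The median fold enrichment was 2.17 in replicate 1 and 2.31 in replicate 2. Only 27.1% and 41.0% of the peaks had a q-value of at most 0.05.

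The peaks of the replicates met mostly at genes. Of the peaks of replicate 2, 4243 (44.8%) overlapped a peak of replicate 1, against a mean of 0.746% after circular shifts (one-sided permutation p = 0.000999, the smallest that 1000 shifts can give). Of the peaks of replicate 1, 4221 (34.1%) overlapped. Peaks of both replicates covered 2.86 Mb, which is 20.6% of the bp covered by either. Shared peaks had their centre at a gene end in 65.1% (replicate 1) and 65.6% (replicate 2) of cases, and peaks without a partner in 19.3% and 20.9%. Shared peaks were also wider, with medians of 907 bp against 483 bp in replicate 1 and 764 bp against 428 bp in replicate 2.

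Fold enrichment was weakly related between replicates over all paired peaks. Across 4143 peaks that paired one to one, Spearman's rho was 0.212 and Pearson's r was 0.165 (permutation p = 1e-05 for each, the smallest that the permutations can give; adjusted p = 1.5e-05 over the chromosome groups). Within chromosomes 6, 9, 14 and 17 rho was 0.566 and r was 0.374 (778 pairs). On the other chromosomes rho was 0.0802 (permutation p = 2e-05) and r was 0.0655 (permutation p = 0.00039) over 3365 pairs, so the pooled value rests largely on the former chromosomes. Their peaks have another relation of fold to p than the rest. Their fold levels differ too. Median folds over all peaks were 1.43 and 1.27 in the blocks described below, and 5.38 and 4.93 among tall chromosome 6 peaks. Such differences in level can raise a correlation over these chromosomes together, and none was computed within each chromosome.

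**Figure D1:**
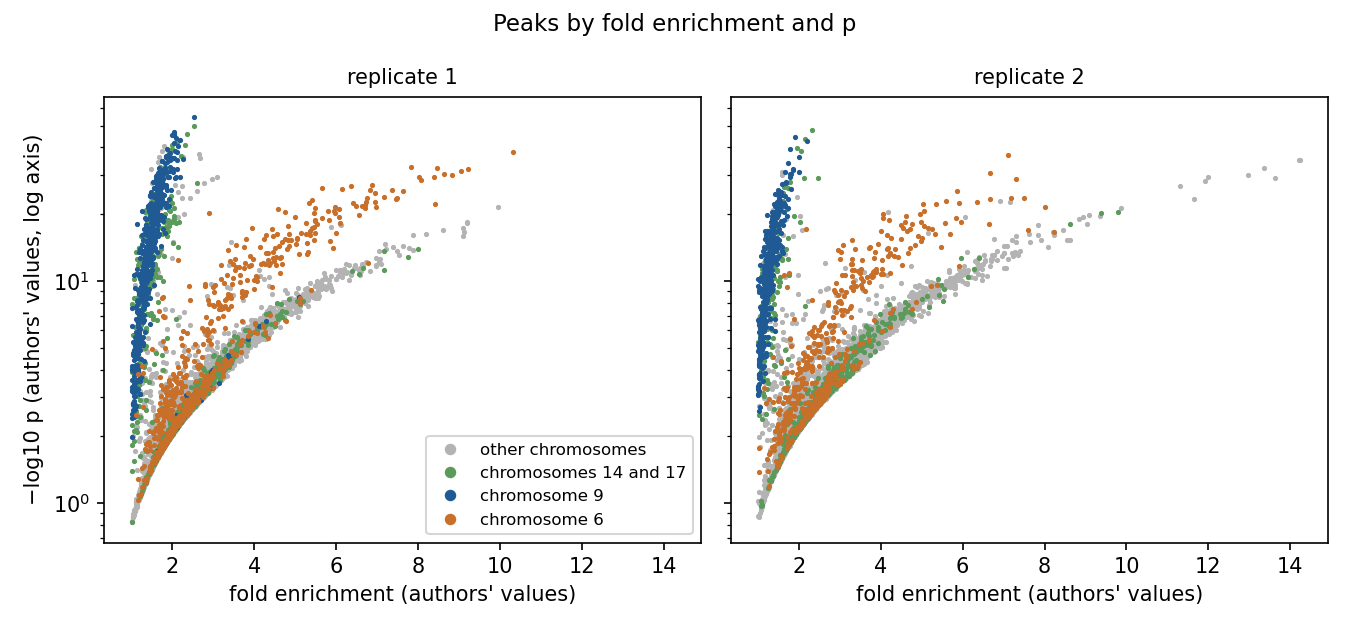
Each point is a peak, with the authors' fold enrichment on the x axis and −log10 p on a logarithmic y axis, for replicate 1 (left) and replicate 2 (right). Peaks of chromosome 9 and part of those of chromosomes 14 and 17 have low folds with small p, and many peaks of chromosome 6 lie above the curve followed by most other peaks.

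Regions shared by the replicates lay mostly at the ends of protein-coding genes. Of the 4200 regions with a peak of each replicate, 65.7% had their centre within 1 kb of a gene end, against 3.17% after circular shifts (20.7 times; one-sided permutation p = 0.000999, the smallest that 1000 shifts can give). A further 19.9% lay elsewhere in a protein-coding gene (38.8% after shifts), 3.86% in another annotated gene (8.08%) and 10.5% outside annotated genes (49.95%). Over all peaks of a single replicate the share at gene ends was lower, 34.9% in replicate 1 and 40.9% in replicate 2. Gene-end peaks were found at 5495 genes in replicate 1, at 4864 in replicate 2 and at 3674 (16.8%) in both.

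Antigen receptor loci were examined because the study concerns the enhancers of Tcrb and of Igk, the immunoglobulin kappa light chain gene used by B cells, and both lie on chromosome 6. In these T cell precursors most of the D-J-C cluster of Tcrb was covered by peaks, and the J-C cluster of Igk had no peak. From Trbd1 to Trbc2 (6, 41533201 to 41548181), 57.9% of the bp were covered in replicate 1, 61.6% in replicate 2 and 52.4% by both, more than in 99.99% of random windows. One peak ran over the Trbj1 segments into Trbc1, the first constant region (41534681 to 41538251 in replicate 1, 41533933 to 41538883 in replicate 2). Another ran over the Trbj2 segments into Trbc2, the second constant region (41542032 to 41547131 and 41542817 to 41547094). Of 13 J segments, 9 lay under a peak in both replicates. The peaks over Trbc1 and Trbc2 were wide and not tall. Their folds were 2.06 and 2.19 in replicate 1 and 2.26 and 2.17 in replicate 2, near the medians of all peaks (2.17 and 2.31). The peaks of replicate 1 over Trbc1 and Trbc2 had −log10 q of only 0.761 and 0.841, so that the cluster had no shared peak with q of at most 0.05. Those of replicate 2 had −log10 q of 2.36 and 14.6, so the loss at that threshold came from replicate 1.

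Upstream in Tcrb, a peak of each replicate overlapped the variable segment Trbv12-2, and different peaks touched Trbv5. The whole locus (40891296 to 41558371) held 8288 bp covered by both replicates, more than 99.4% of random windows. The interval from Trbc2 to Trbv31 (41548182 to 41557692), which holds the beta enhancer E-beta, had no peak in replicate 1. Replicate 2 had a peak of 1382 bp there (41554024 to 41555405) with a fold of 1.65, −log10 p of 10.7 and −log10 q of 8.47. A fold under 2 with a −log10 p of at least 5 also marks the blocks described below, none of which lies on chromosome 6.

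At Igk (6, 67555636 to 70726754), peaks of both replicates covered 553 bp, at 68011686 to 68012238, 4503 bp from Igkv1-122. None of the 102 variable, 5 joining and 1 constant segments lay under a peak in either replicate. No peak of either replicate lay in the J-C cluster, between Igkj5 and Igkc, where the intronic kappa enhancer lies, or between Igkc and Rpia (70726755 to 70765719), which holds the 3' kappa enhancer and Ed. The covered bp of the Igk locus exceeded 17.8% of random windows. Tcrb and Igk were set side by side as single loci, and no test of their difference was made. The empty Igk intervals span 2.51 to 39.0 kb, and chromosome 6 had 1172 bp covered by both replicates per Mb. How many random windows of those sizes are empty was not computed. The E-beta interval of Tcrb had 0 bp covered by both replicates as well, so absent peaks there do not establish absent acetylation at Igk.

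**Figure D2:**
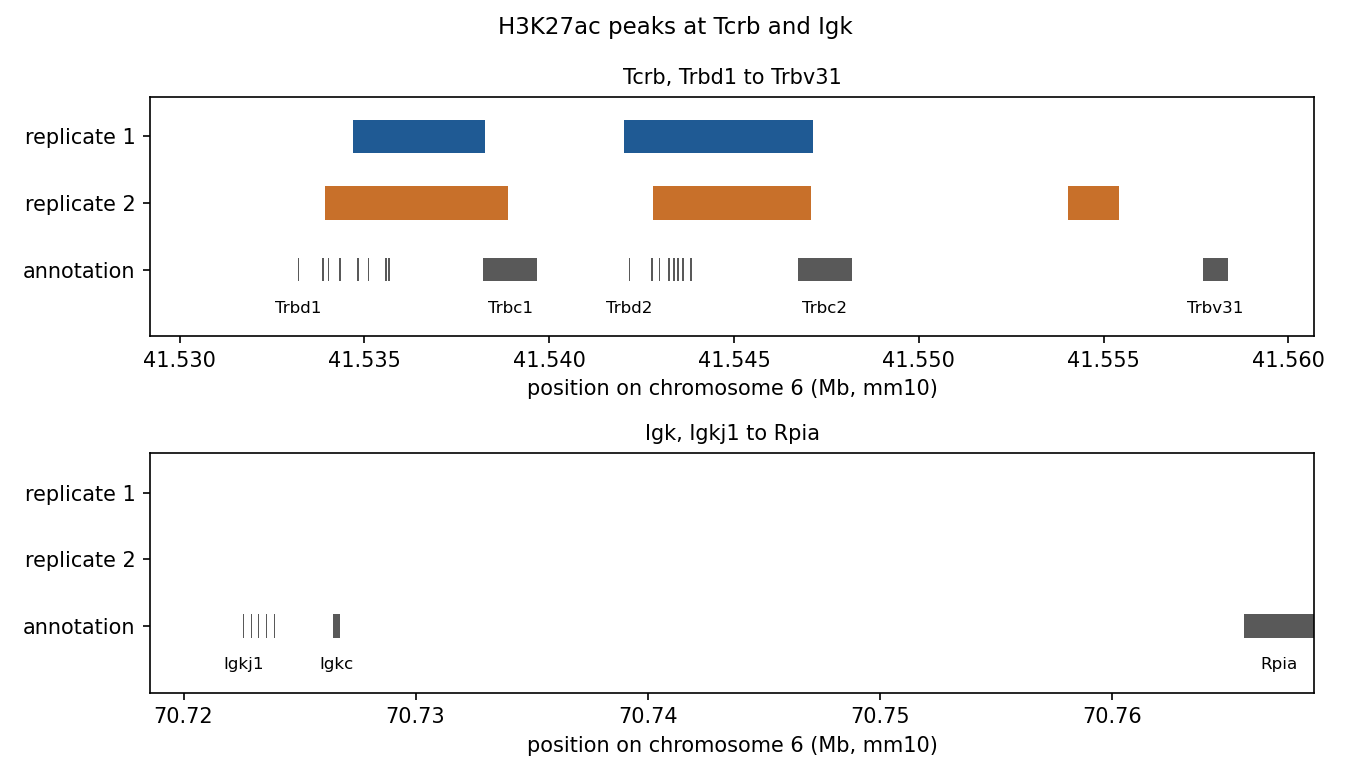
Peaks of replicate 1 and replicate 2 (bars) above annotated segments and genes, by position on chromosome 6 in Mb, for Tcrb from Trbd1 to Trbv31 (top) and Igk from Igkj1 to Rpia (bottom). Both replicates have 2 peaks in the Tcrb cluster, replicate 2 has 1 more before Trbv31, and neither has a peak in the Igk interval.

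Among the other receptor loci, Tcrg, the T cell receptor gamma locus, was densely acetylated among all listed peaks, though no shared coverage was left with q of at most 0.05 or 1e-05. Peaks of both replicates covered 12131 bp, or 6.96% of the locus (13, 19178042 to 19352343), more than in 99.9% of random windows. The constant regions Trgc1, Trgc2 and Trgc4 and the variable segment Trgv1 lay under peaks of both. In the Tcra and Tcrd locus (14, 52427967 to 54224198) both replicates covered 2534 bp. Peaks of both overlapped Trav15d-2-dv6d-2, Trav13d-3, Trav15n-2 and Trav13n-3, and a shared peak lay near Trdj1, at 656 bp from it in replicate 1 and 485 bp in replicate 2. The peak near Trdj1 had −log10 q of 5.56 and 3.29. At none of those variable segments did the peaks of both replicates have q of at most 0.05. The alpha chain cluster from Traj61 to Trac had no peak in either replicate. The interval from Trac to Dad1, which holds the alpha enhancer, had a single peak of 288 bp in replicate 2. At the immunoglobulin heavy chain locus, the 1087 bp covered by both replicates lay between Ighm and Ighj4 (12, 113424262 to 113425348), the interval of the enhancer E-mu, 1531 bp from Ighm. They made up 18.8% of that interval, more than in 99.9% of random windows. The peaks there had −log10 q of only 0.858 in replicate 1 and 0.842 in replicate 2, so neither had q of at most 0.05.

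Whether chromosome 6 as a whole stood apart depended on the peaks counted. With all peaks it had 1172 bp covered by both replicates per Mb, rank 10 of the autosomes, and its rank was 14 in replicate 1 and 13 in replicate 2. With q of at most 0.05 or 1e-05 it ranked 2, and it held 36.2% and 17.9% of the peaks with a fold of at least 4 and a −log10 q of at least 5. Among all peaks, chromosome 11 was first with 2017 bp per Mb. It also had 13.2 protein-coding genes per Mb against 7.53 on chromosome 6. Per protein-coding gene the 2 were close, at 153 bp and 156 bp, and chromosome 13 was first with 187 bp. Along chromosome 6, the 1 Mb bin that starts at 41 Mb had 8288 covered bp, all of them in Tcrb, the second highest after the bin at 47 Mb with 29318 bp.

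Gene lists showed which programmes carried gene-end acetylation. Genes of proliferation, housekeeping and T lineage regulation were acetylated more often than other genes, and 5 of the 18 lists passed the adjusted Fisher's exact test, all upward. With a peak in both replicates, 0 were lower, also at an unadjusted p under 0.05. That count says little: even 0 acetylated members gave lists of 13 to 16 genes an unadjusted Fisher's exact p of at least 0.0917. With a peak in either replicate, the erythroid and megakaryocyte, thymic stroma and unrelated tissue lists were lower (adjusted Fisher's exact p = 0.0300, 0.0217 and 0.0217). Among housekeeping genes 9 of 15 were acetylated (against 16.8% of other genes, adjusted Fisher's exact p = 0.00347). Rpl13a had an acetylated length of 1984 bp and Gapdh had 1877 bp. Among cell cycle genes 9 of 16 were acetylated (56.2%, adjusted Fisher's exact p = 0.00347). They were led by Cdk6 (2170 bp), a kinase of G1, Mcm6 (2022 bp), part of the replicative helicase, and Ccnd2 (1232 bp), a D-type cyclin.

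T lineage transcription factors were acetylated in 8 of 17 cases (47.1%, adjusted Fisher's exact p = 0.0217), with 12 in replicate 1 and 9 in replicate 2. Tcf7, which encodes TCF-1, had 3338 bp and Ikzf1, which encodes Ikaros, had 3242 bp. Bcl11b, a factor of T cell commitment, had 2441 bp within 25 kb but a gene-end peak in replicate 1 alone. End joining and break repair genes, which act on the breaks made during receptor rearrangement, were acetylated in 6 of 13 cases (46.2%, adjusted Fisher's exact p = 0.0471), among them Xrcc4, where the peaks of the replicates did not overlap. Prkdc had 1048 bp and Trp53 had 784 bp, and Xrcc6 had 5218 bp within 25 kb but no gene-end peak. Cytokine signalling and survival genes were also acetylated in 6 of 13 cases (adjusted Fisher's exact p = 0.0471), with 2424 bp at Ifngr1, 1563 bp at Mcl1, which had a gene-end peak in replicate 1 alone, and 1160 bp at Bcl2. The T lineage, end joining and cytokine lists all missed the threshold without chromosomes 6, 9, 14 and 17, a run chosen after seeing the data, where their shares were 42.9%, 45.5% and 50% (adjusted Fisher's exact p = 0.0777, 0.0777 and 0.0509). The end joining and cytokine lists also missed it with the 10000 peaks of smallest p (38.5% against 14.4% of other genes, adjusted Fisher's exact p = 0.105 each) and with a background without receptor genes (46.2% against 18.0%, 0.0662 each). So did the cytokine list with replicate 2 alone (46.2% against 22.2%, 0.0822). With q of at most 1e-05, where 160 genes were acetylated, no list passed. With q of at most 0.05, where 577 were, only T identity did (22.2% against 2.62%, adjusted Fisher's exact p = 0.0196). Its 4 acetylated members were Cd27 on chromosome 6 and the adjacent Cd3d, Cd3e and Cd3g, where chromosome 9 has low folds with small p. Cd3d and Cd3g share a replicate 1 peak, so these members are not independent. With all peaks and without chromosomes 6, 9, 14 and 17, T identity had 0 of 13. The 5 lists that passed with all peaks had 0 to 2 acetylated members each at these thresholds. At 1e-05 they included 1 of 17 T lineage and 1 of 15 housekeeping genes against 0.727% of other genes, and at 0.05 they included 2 of 16 cell cycle and 2 of 15 housekeeping genes against 2.63%.

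Lists of T cell identity and of the double-negative stage did not pass. Of 18 T identity genes 4 were acetylated (22.2%, adjusted Fisher's exact p = 0.558): Cd3d, Cd3e and Cd3g, the adjacent genes of the CD3 chains on chromosome 9, and Cd27 on chromosome 6. Cd247, the CD3 zeta chain, had the greatest length of the list (1510 bp), with a gene-end peak in replicate 2 alone. Of 14 genes of the double-negative stage, Dntt, which encodes terminal transferase and had 1965 bp, and Cxcr4 (1408 bp) were acetylated, and Il2ra, which encodes CD25, had 532 bp and a gene-end peak in replicate 2 alone. Rag1 and Rag2, which encode the recombinase, had no gene-end peak in either replicate. They and Cd4 and Cd8a below were named after their values were seen. Notch pathway genes were acetylated in 5 of 16 cases (adjusted Fisher's exact p = 0.217), with 1192 bp at Psenen, whose gene-end peak was in replicate 1 alone, 818 bp at Hes5 and 745 bp at Ncstn. Chromatin and architecture genes were acetylated in 5 of 14 cases (adjusted Fisher's exact p = 0.165), led by Ctcf (2139 bp), Stag2 (1654 bp) and Ep300 (1621 bp). That list passed within 2.5 kb (57.1% against 18.9%, adjusted Fisher's exact p = 0.00614), with replicate 2 alone (57.1% against 22.2%, 0.0197) and with a peak in either replicate (64.3% against 30.5%, 0.0310).

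Lists of other stages and cell types had 0 or 1 acetylated member each, and none of these lists differed from other genes after adjustment. None of 16 later thymocyte genes, among them Cd4 and Cd8a, was acetylated in both replicates (adjusted Fisher's exact p = 0.165), nor any of 14 effector T genes (adjusted Fisher's exact p = 0.204). With a peak in either replicate, later thymocyte genes stood at 25% and the NK list below at 21.4%, against 30.5% of other genes (adjusted Fisher's exact p = 0.789 and 0.606). Of 16 progenitor genes only Kit, a receptor of early progenitors, was acetylated (adjusted Fisher's exact p = 0.558), and of 14 genes of NK cells, innate lymphoid cells and gamma-delta T cells only Nkg7 (adjusted Fisher's exact p = 0.558), where the peaks of the replicates did not overlap. None of the B cell, myeloid, erythroid and megakaryocyte, thymic stroma or unrelated tissue genes was acetylated. Some genes of these lists had no gene-end peak in both replicates but shared peaks within 25 kb. They were Flt3 (1261 bp), Nfe2 (1223 bp) and Bcl11a (835 bp) of the progenitor list, Cd79a (1223 bp), Igll1 and Vpreb1 (1186 bp each) of the B cell list, and Tyrobp (2257 bp), Klrb1c (1141 bp) and Rora (366 bp) of the NK list. Cebpe (1067 bp), Cd68 (649 bp) and Elane (502 bp) of the myeloid list and Gp1ba (2131 bp), Epor (432 bp) and Hba-a1 (324 bp) of the erythroid and megakaryocyte list were alike in this. So were Aire (379 bp), Epcam (237 bp) and Pecam1 (107 bp) of the stroma list and Gfap (298 bp) of the unrelated tissues. At a count of 0 the smallest unadjusted Fisher's exact p of these short lists was 0.0917, so with a peak in both replicates none could have been called lower.

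**Figure D3:**
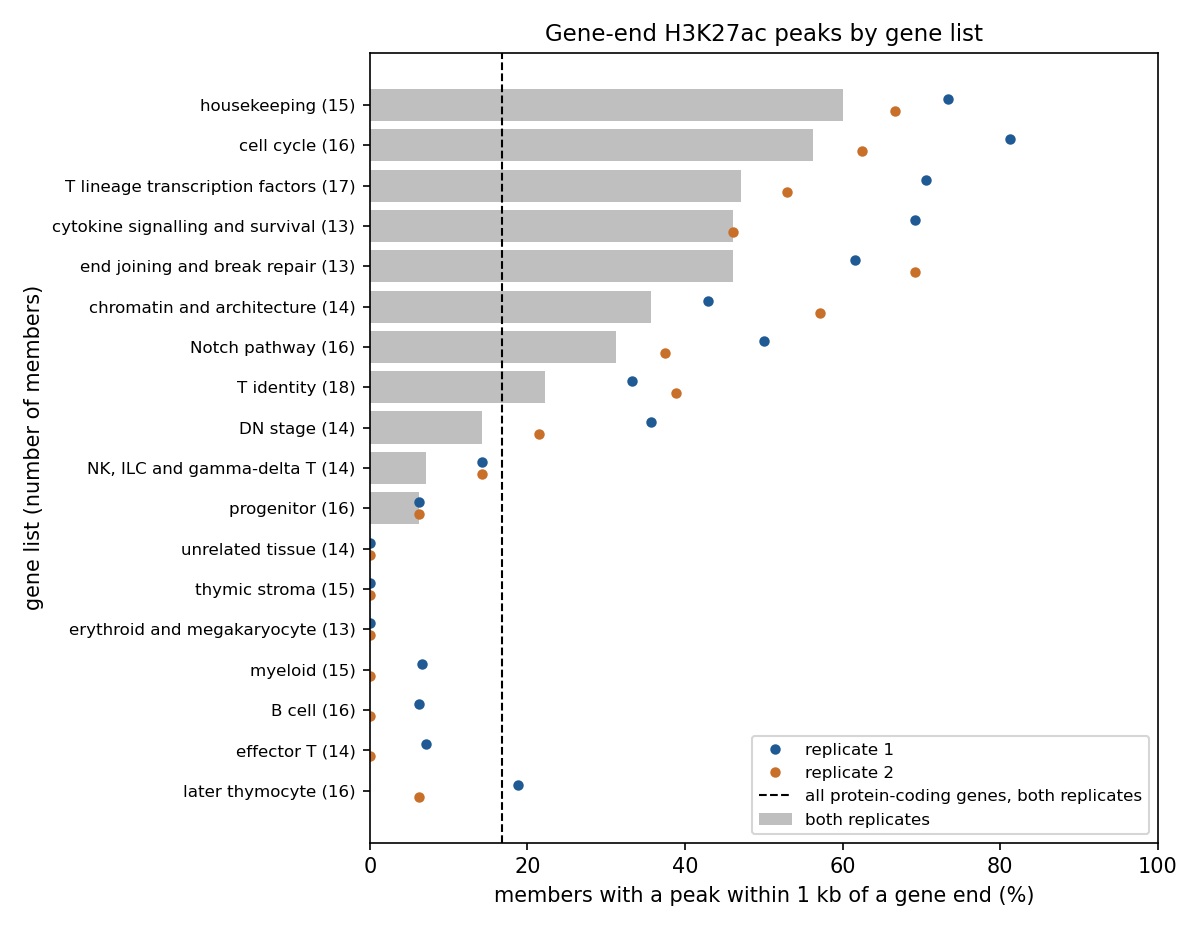
Percent of the members of each gene list with a peak within 1 kb of a gene end, for both replicates (bars) and for replicate 1 and replicate 2 alone (points), with the number of members in parentheses and the share of all protein-coding genes as a dashed line. Housekeeping (9 of 15) and cell cycle genes (9 of 16) are highest, and 7 lists are at 0 for both replicates.

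Direct comparisons between lists had the same direction and did not pass after adjustment over the 3 with all peaks and a window of 1 kb. T lineage transcription factors exceeded progenitor genes by 40.8 percentage points (8 of 17 against 1 of 16, Fisher's exact p = 0.0167, adjusted p = 0.0501). T identity genes exceeded B cell genes by 22.2 points (4 of 18 against 0 of 16, Fisher's exact p = 0.105, adjusted p = 0.158), and without chromosomes 6, 9, 14 and 17 that difference was 0. Genes of the double-negative stage exceeded later thymocyte genes by 14.3 points (2 of 14 against 0 of 16, Fisher's exact p = 0.209, adjusted p = 0.209). With replicate 1 or replicate 2 alone the first comparison passed (adjusted Fisher's exact p = 0.000696 and 0.0121), as it did with a peak in either replicate (0.000177), within 2.5 kb (0.0198) and with the 10000 peaks of smallest p (0.00803). It did not pass without chromosomes 6, 9, 14 and 17 (6 of 14 against 1 of 14). Nor did it pass with q of at most 0.05 or 1e-05 (1 of 17 against 0 of 16 at each). A background without receptor genes left the first comparison at 8 of 17 against 1 of 16. That run is no further check, since the direct comparisons use list members alone. The second passed with replicate 2 alone (0.0121) and with a peak in either replicate (0.0118), and not with replicate 1 alone (0.135).

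Acetylated length was compared among genes with a gene-end peak in both replicates. The 8 acetylated T lineage transcription factors had a median of 1778.5 bp against 665.5 bp for other acetylated genes (permutation p = 0.00468, adjusted p = 0.0374), the only 1 of 8 lists to pass. The 5 chromatin and architecture genes had a median of 1621 bp (permutation p = 0.0201, adjusted p = 0.0804). With windows of 10 kb and 100 kb the T lineage list did not pass, with medians of 1350.5 bp against 579 bp and 1941 bp against 1096 bp (adjusted permutation p = 0.138 and 0.264).

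Joining neighbouring peaks gave 3929 regions, of which 78 were large in both replicates. The first was a cluster of 5S ribosomal RNA genes on chromosome 8 (123559573 to 123622584), and ranks 2 and 4 were regions of chromosome 6 (47737612 to 47773168 and 47650864 to 47686832) with Rn4.5s, Gm40363, Gm40364, Gm40365, Gm40367, Gm40369 and Gm36327. Histone gene clusters of chromosome 13 took ranks 6, 11 and 19. Rank 6 held H4c8, H2ac10, H3c8, H2bc9, H3c7, H4c6, H1f3, H3c6, H2ac8, H2bc8, H2bc7, H2ac7, H3c4, H4c4 and H2bc6. Rank 11 held H1f2, H3c3, H2bc3, H2ac4, H3c2, H4c2, H4c1, H3c1 and H1f1, and rank 19 held H2ac15, H2bc15, H1f5 and H3c11. The Tcrb cluster was at rank 9 (41533933 to 41547131), and the end of Tcrg with the neighbouring Stard3nl at rank 16. Other regions held Rhoh, which encodes a GTPase of blood cells (rank 13), Cdkn1b, which encodes the cell cycle inhibitor p27 (rank 18), Isy1, Cnbp and Gm44064 (rank 10), Hnrnpf and 4933440N22Rik (rank 15), Tmem69 and Gpbp1l1 (rank 20), Mid1 (rank 8), Gm21119 (rank 5), and Gm51591 and Gm51573 (rank 12). Several of these are repeated genes, where reads may be shared between copies. Ranks 3 (9, 3000073 to 3038323), 14 and 17 held no end of a protein-coding gene and no other annotated gene. Peaks covered rank 3 nearly end to end (38251 and 38153 bp of 38.3 kb), and rank 17 likewise (5584 and 5451 bp of 5.58 kb). No regions of known artifact signal were removed here, so these may not be acetylated regions, which was not tested. Rank 7, on chromosome Y, held Mid1-ps1 and no end of a protein-coding gene. No list was more frequent in large regions with both replicates (0 of 12 at an unadjusted Fisher's exact p under 0.05), while with replicate 1 alone the cytokine list was (4 of 9 genes against 6.67%, adjusted Fisher's exact p = 0.0308). The tallest shared peaks lay 26.0 kb from Trim33 (3, 103383878 to 103385710, folds 6.17 and 9.04), at the end of Isy1 (6, 87838238), inside Mical3 (6, 120966740), in Arhgap25 (6, 87531627) and in Irf1 (11, 53770009), an interferon regulatory factor.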

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

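Peaks outside the assembled chromosomes entered no comparison. Replicate 1 had 75 of them and replicate 2 had 55, both above 3, the limit that a count of 0 allows, which is what brought them up. They lay on 13 unplaced or unlocalised sequences, of which 11 had peaks in both replicates. No explanation was tested.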

How the results depend on the processing

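The runs with q of at most 0.05 and without chromosomes 6, 9, 14 and 17 were chosen after seeing the data. The replicate overlap, the fold correlation and the share of regions at gene ends kept their direction and stayed past their threshold in every alternative run: overlap from 16.8% to 44.8%, rho from 0.0802 to 0.690, gene ends from 34.9% (all peaks of replicate 1) to 73.6% (within 2.5 kb). The number of raised lists, the length call and the receptor loci depended on the peak threshold.

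With q of at most 1e-05, 0 lists were raised against 5, but only 160 of 21887 genes were acetylated, too few to read a direction from a list with 0 members. There no list had the 3 acetylated members that the length test needs, the Tcrb D-J-C cluster and Tcrg had 0% shared coverage, chromosome 6 ranked 2, and 5 joined regions were large against 78. With q of at most 0.05, 1 list was raised (T identity, through the adjacent Cd3d, Cd3e and Cd3g on chromosome 9 and Cd27 on chromosome 6). The same list alone could be tested for length and 0 passed. The Tcrb cluster and Tcrg had 0% shared coverage, chromosome 6 ranked 2, and 13 regions were large. Fewer peaks pass these thresholds (984 and 895, or 3352 and 3887, in the replicates).

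With the 10000 peaks of smallest p, which changes replicate 1 only, 3 lists were raised (end joining and cytokine lost), 0 differed in length, chromosome 6 ranked 9, and T lineage transcription factors exceeded progenitor genes by 47.1 points and passed. They also passed within 2.5 kb (46.7 points) and with a peak in either replicate (70.2 points), where T identity exceeded B cell genes by 43.8 points and passed, 3 lists differed in length, and coverage was 67.1% in the Tcrb cluster, 0.263% in Igk and 15.6% in Tcrg. Of those 3 lists, T lineage and cytokine had greater lengths than other genes, and later thymocyte had smaller ones (median 348 bp against 1416 bp). A background without receptor genes gave 3 raised lists, the same 2 lost. Windows of 10 kb and 100 kb gave 0 lists that differed in length. Without chromosomes 6, 9, 14 and 17, 2 lists were raised (cell cycle and housekeeping), and Tcrb, Igk and the rank of chromosome 6 have no value.

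With one replicate alone, T identity exceeded B cell genes by 27.1 to 38.9 points and T lineage transcription factors exceeded progenitor genes by 46.7 to 64.3 points. The latter passed with each replicate and the former with replicate 2 only. The length test called 2 lists with each replicate, T lineage transcription factors in both cases. The other list was cytokine with replicate 1 (adjusted permutation p = 0.007) and double-negative stage with replicate 2 (3 genes, 0.028). Coverage was 57.9% to 61.6% in the Tcrb cluster, 0.0725% to 0.208% in Igk and 9.58% to 12.96% in Tcrg, chromosome 6 ranked 13 to 14, and 321 to 346 regions were large. The cause was not tested, except that one replicate or either covers more bp than both by construction. Of 218 comparisons for single lists, 188 kept their call at the threshold, 9 passed only in the alternative and 21 passed only without it. Among the 21, 2 also reversed direction: the cell cycle and cytokine lists with q of at most 1e-05, where each had 0 acetylated members. The 5' end alone and CpG strata were not run. No paired analysis was possible because there is 1 H3K27ac group. The unknown depth limits all counts of absent peaks.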

Other observations

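The gene classes, the pooled list and the check without receptor genes in this part were chosen after the values were seen, as were the test of stronger acetylation in the blocks and the comparison of tall peaks with shifted positions. The other tests were written down before their result was seen, on blocks and tall peaks defined from these data.

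Gene classes outside the planned lists differed widely in gene-end peaks, and no test was made. Of 67 replication-dependent and linker histone genes 51 (76.1%) had a gene-end peak in both replicates, and of 81 ribosomal protein genes 53 (65.4%), against 16.8% of all protein-coding genes. Of 63 annotated ribosomal RNA genes 32 (50.8%) and of 408 transfer RNA genes 32 (7.84%) had one. Only 1 of 1110 olfactory receptor genes and 0 of 39 Hox genes did. Many genes of the histone and ribosomal RNA clusters are near-identical copies or neighbours, so these counts are not of independent genes.

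Some of the lists with 0 or 1 acetylated member were pooled. Of 87 genes of B cells, myeloid cells, NK and innate lymphoid cells, erythroid cells and megakaryocytes, thymic stroma and unrelated tissues, 1 (1.15%, Nkg7) had a gene-end peak in both replicates, against 16.8% of other genes (Fisher's exact p = 3.94e-06). There were 4 in replicate 1 and 2 in replicate 2. Each pooled list had already been seen to hold 0 or 1 acetylated member, so this p restates those counts and is no separate support. The progenitor, later thymocyte and effector T lists, with 1, 0 and 0 acetylated members, were left out of the pool. The pool held no shared member with q of at most 0.05, where other genes stood at 2.65% (Fisher's exact p = 0.177).

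The first pattern is a set of blocks, 11 in number and 130 Mb in all, joined from bins of 2 Mb where at least 50% of the peaks of each replicate have a fold under 2 with a −log10 p of at least 5. They take in most of chromosome 9, 14 from 24000001 to 46000000 and 17 from 24000001 to 30000000, and hold 54.3% (replicate 1) and 38.8% (replicate 2) of the peaks with q of at most 1e-05. Random placement is argued against, since block peaks lay at gene ends at least 11.4 times as often as after shifts. Stronger acetylation stays open, since the blocks were picked by low fold and their median folds (1.43 and 1.27 against 2.20 and 2.35 elsewhere) follow from that choice. A raised local background that hides weak peaks remains a candidate explanation: 14.7% of genes in blocks had a gene-end peak in both replicates against 16.9% elsewhere (Fisher's exact p = 0.0409), and 15.3% against 18.2% without receptor genes (Fisher's exact p = 0.00948), and no other biological explanation was tested. Genes of a block are neighbours, and these p-values treat them as independent. They do not measure the spread between regions of the genome.

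The second pattern is a run of tall peaks on chromosome 6, with a fold of at least 4 and a −log10 q of at least 5: 111 of 307 such peaks in replicate 1 and 66 of 368 in replicate 2. Reads of another library placed without regard to genes are argued against as the whole cause: tall peaks lay at gene ends in 33.3% of cases in replicate 1 (95% interval 24.7% to 42.9%) and 57.6% in replicate 2 (44.8% to 69.7%), at least 12.1 times as often as after shifts (2.75% and 2.87%). The comparison written down beforehand, with other chromosome 6 peaks (34.4% and 38.5%), met neither of its bounds in both replicates. Acetylation shared by both cell samples stays open, since 32.4% of tall peaks (95% interval 23.9% to 42.0%, which gives no direction) overlapped the other replicate against 34.5% of peaks of other autosomes in replicate 1 (ratio 0.94) and 59.1% against 45.5% in replicate 2. Tall peaks of other autosomes overlapped in 29.1% and 46.5% of cases, and reads of another library that follow genes were not tested.

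The third pattern is on chromosome Y, with 149 peaks in replicate 1 and 48 in replicate 2 (1.20% and 0.506% of peaks, Fisher's exact p = 2.91e-08). More cells from males in replicate 1 may account for it, and of the Y genes Kdm5d, Ddx3y, Uty and Eif2s3y only Uty had a gene-end peak, 1 gene in replicate 1 and the same gene in replicate 2. Equal counts had been written down beforehand as counting against this explanation, but 1 of 4 genes in each replicate is a difference smaller than any spread these 4 genes could show, so the bound was set too loosely and the explanation stays open. Only 8 of the 149 peaks overlapped a peak of replicate 2. The share of peaks on chromosome X was 2.45% and 3.80%.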
